A study of Mus musculus with 10 samples.

How the data were processed

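RNA from adipose tissue of mice and from brown adipocytes in culture was measured on 10 one-colour microarrays that carry probes for long non-coding RNAs and for protein-coding transcripts (Arraystar mouse lncRNA design on an Agilent slide, per the labels). Labelled Cy3 cRNA was made from total RNA, per the labels. Samples were grouped by their titles into saline-injected brown fat (2 arrays), saline-injected white fat (2 arrays), white fat from mice injected with the β3-adrenergic agonist that the labels call CL (2 arrays), and brown adipocytes at days 0, 3, 5 and 7 of differentiation (1 array per day).

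Per the file headers, the deposited scanner files hold spot intensity values from Agilent Feature Extraction 11.0.1.1, namely a background-subtracted processed signal, the median spot and local background brightness, and flags of 0 or 1 for spots well above background, outlier spots and saturated spots. The submitters' processing notes name version 9.1 of the same program, and which version made the final values stays open. A deposited value table holds log2 values for 18997 of the probes, and the authors' steps behind it are not given in the sources used here. Set against the scanner values, each column of that table followed the log2 signal of its own array, quantile-normalized over all arrays, at r of 1.00. Each also followed the log2 signal before normalization, at r of 0.999 to 1.00, so these correlations cannot show which normalization was used. Column medians were 7.45 and 7.42 (brown fat), 7.20 and 7.30 (white fat, saline), 7.15 and 7.41 (white fat, CL), and 7.38, 7.36, 7.37 and 7.45 (days 0, 3, 5 and 7). The scale and direction of the table are therefore settled, and its normalization and centring are unknown. Every probe it lists was well above background on at least 5 of the 10 arrays.

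Signals were analysed in R 4.3.3 with limma 3.58.1. Control spots and the 1200 spots of 20 negative control probes were left out, as were spots with an outlier flag, and saturated spots would have been kept (there were 0). Spots of 1 probe were averaged on the log2 scale, which left 59709 probes. Values are log2(processed signal) minus the 75th percentile of the array. A probe was tested in the tissues when it was well above background on both arrays of at least 1 of the 3 tissue groups. One limma model (lmFit and eBayes) was fitted to the 6 tissue arrays with group means only, which left 3 residual degrees of freedom and a prior of 4.46, and Benjamini-Hochberg adjustment ran over the 43542 probes tested. A probe was called at an adjusted p under 0.05, two-sided. A probe that was not well above background on any array of a group has only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, written as at least N-fold. These bounds hold for the main setting, and with normexp correction every probe named with a bound had a smaller fold.

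The 4 cell arrays have no replicate. The only test on them was a limma linear trend on the day, run as an alternative. In the main setting a probe was counted as raised or lowered when it was at least 2-fold above or below day 0 on each of days 3, 5 and 7, among probes well above background on at least 1 of the 4 arrays. Fisher's exact tests on counts of probes treat probes as independent, which probes of related transcripts are not.

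The scanner files give most probes a design number and no gene. Through a table of RefSeq transcripts (assembly GRCm38.p6, used for names only because the design is annotated on mm9), 116 of 123 probes with a RefSeq accession received 1 gene symbol, 0 received several, and 59593 probes stayed without a symbol. Of 486 entries on 24 gene lists (thermogenic, beige, white fat, mitochondrial, lipid, cell type, cell cycle, stress and interferon genes, and named long non-coding RNAs), 1 was measured under its name, the glycerol kinase gene Gk, and 0 lists reached the 5 members needed for a list test. The list tests, their alternatives and the random-list percentiles were therefore not run. Ucp1, Cidea, Lep, Adipoq and AK038898 were to be named in every case and were not measured under those names.

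Probe classes were inferred. None of the 118 probes with an NM accession and all 5 with an NR accession are in the value table, and a run of 24592 design numbers without a single listed probe, of which 13545 were well above background on all 10 arrays, was taken with the NM probes as the mRNA class (24710 probes). The non-coding class (34487 probes) holds most other design numbers (26832) and probes of lincRNA loci (5351), transcript accessions (1344) and ultraconserved elements (960). These are counts of probes, and 2663 lincRNA loci had a probe on each strand. The other 512 probes were left unclassified, being outside the value table and either well above background on all 10 arrays or transcript accessions on custom probes without an NR number.

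The design, the alternatives and the rule for named transcripts were fixed before the data were examined. The rule names, per tissue comparison, the 8 largest rises and 8 largest falls among called protein-coding probes with a symbol whose replicates do not overlap, and the 5 and 5 among non-coding probes with a transcript accession. For differentiation it takes the same numbers by the change from day 0 to day 7. Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the value table, no filter or a stricter filter on dim probes, the replicate number as a block, a fold minimum, a trended robust prior, array weights, a fit of the compared groups alone and leaving out each array in turn. The normexp correction used the median spot signal, in place of the mean signal that was planned.

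The fit was tested on simulated data with the real means and spreads, the CL pair's wider spread included, over 43444 probes with 50 changed probes per fold size. For brown against white fat it called 0, 1, 37 and 47 of the 50 at log2 changes of 1, 2, 3 and 4, with 0 unchanged probes called. For CL against saline white fat it called 0, 4, 38 and 42, with 7 unchanged probes called. For CL-treated white fat against brown fat it called 0, 3, 35 and 45, with 19 unchanged probes called. False calls exceeded the nominal share in both comparisons with CL. The simulation changed only 50 probes per fold size. In the data 4526 probes were called between brown and white fat, and 1521 between CL-treated white fat and brown fat. Benjamini-Hochberg adjustment is less strict when more probes change. The simulated counts therefore do not give the power or the false calls of these real comparisons. The differentiation count found 11, 44, 50 and 50 of the 50, and 2.14% of unchanged probes were counted as changed. Figures were drawn with Python and matplotlib 3.10.9.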

Results

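Long non-coding and coding RNA was profiled on 10 arrays, 1 per sample: fat from mice injected daily for 7 days with saline or with the compound the labels call CL (1 mg/kg), an agonist of the β3-adrenergic receptor that stimulates thermogenesis in fat, and brown adipocytes differentiating in culture for 7 days. The tissue groups were brown fat after saline, white fat after saline and white fat after CL, with 2 arrays each, which the labels call biological replicates without saying whether each was 1 mouse. The cells had 1 array each at days 0, 3, 5 and 7. Between 55.2% (a brown fat array) and 78.3% (day 3) of the 59709 probes were well above background, where 10.9% to 36.4% of negative control spots carried the same mark. Replicate arrays correlated at r = 0.983 in saline white fat, 0.980 in brown fat and 0.939 in CL-treated white fat across tested probes. Each CL array correlated more with both saline white fat arrays (r = 0.951 to 0.977) than with the other CL array, which limits every comparison with CL. The share of probes 2-fold apart between replicates was 4.42% in saline white fat, 8.86% in brown fat and 35.0% in CL-treated white fat. All 6 tissue arrays were scanned together, the saline arrays in column 1 of the slide and the CL arrays in column 2, so treatment and slide column cannot be told apart. In column 1 brown fat held rows 1 and 2 and white fat rows 3 and 4, so tissue and slide row cannot be told apart either. From row 1 to row 4 of that column 55.2%, 67.8%, 74.0% and 77.3% of probes were well above background. The number of arrays limits the precision of every value below.

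The first comparison asked which transcripts separate brown from white fat. Gk, glycerol kinase, which phosphorylates glycerol for reuse in lipid synthesis, was 5.37-fold higher in brown fat (log2 fold change 2.42, SE 0.34, limma adjusted p = 0.0117), at 0.69 ± 0.15 in brown fat and -1.73 ± 0.09 in white fat (log2 signal relative to the 75th percentile of the array, mean ± SD, n = 2 each). Among non-coding transcripts, BC156060 was at least 112-fold higher in brown fat (limma adjusted p = 0.000766), since it was not well above background on either white fat array, and its log2 difference with normexp was 4.762, below that bound. AK138758 was 19.5-fold higher (log2 4.29, SE 0.40, limma adjusted p = 0.00376). DV062790, AK138450 and AI507368 were higher by log2 3.73, 3.70 and 3.69.

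Other transcripts were lower in brown fat than in white fat. AK196148 was 25.3-fold lower in brown fat (log2 -4.66, SE 0.41, limma adjusted p = 0.00327), at -1.23 ± 0.58 against 3.43 ± 0.16 in white fat (n = 2 each). DV650143 and AK015763 were not well above background on either brown fat array and lay at least 11.5-fold and at least 6.44-fold lower there (limma adjusted p = 0.0357 and 0.0127), with normexp log2 differences of -1.978 and -1.41 that are smaller than these bounds. AK145170 fell by 3.63 and AA797690 fell by 3.32 on the log2 scale from white to brown fat, each well above background on 1 of the 2 brown fat arrays. Their log2 differences with normexp were smaller, at -1.514 and -1.246. Among symbol-bearing probes, those for Ccl21b, Ccl21c and Gm13304 were lower in brown fat by log2 -2.68, -2.42 and -2.61 (limma adjusted p = 0.0293, 0.0387 and 0.0301). Ccl21 chemokines draw lymphocytes and dendritic cells through the receptor Ccr7, and their genes are near-identical copies, so these probes cannot be assigned to 1 copy with certainty. Pramel39, of the multi-copy PRAME-like family, and the predicted genes Gm4312 and Gm16367 were also lower, by log2 -2.37, -2.10 and -2.04, and Pramel39 and Gm16367 were well above background on 1 of the 2 brown fat arrays. With normexp the log2 differences of Pramel39, Gm4312 and Gm16367 were -1.092, -1.848 and -1.285. In all, 1 of the 112 symbol-bearing probes tested was higher in brown fat, 6 were lower and 105 were not called.

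**Figure D1:**
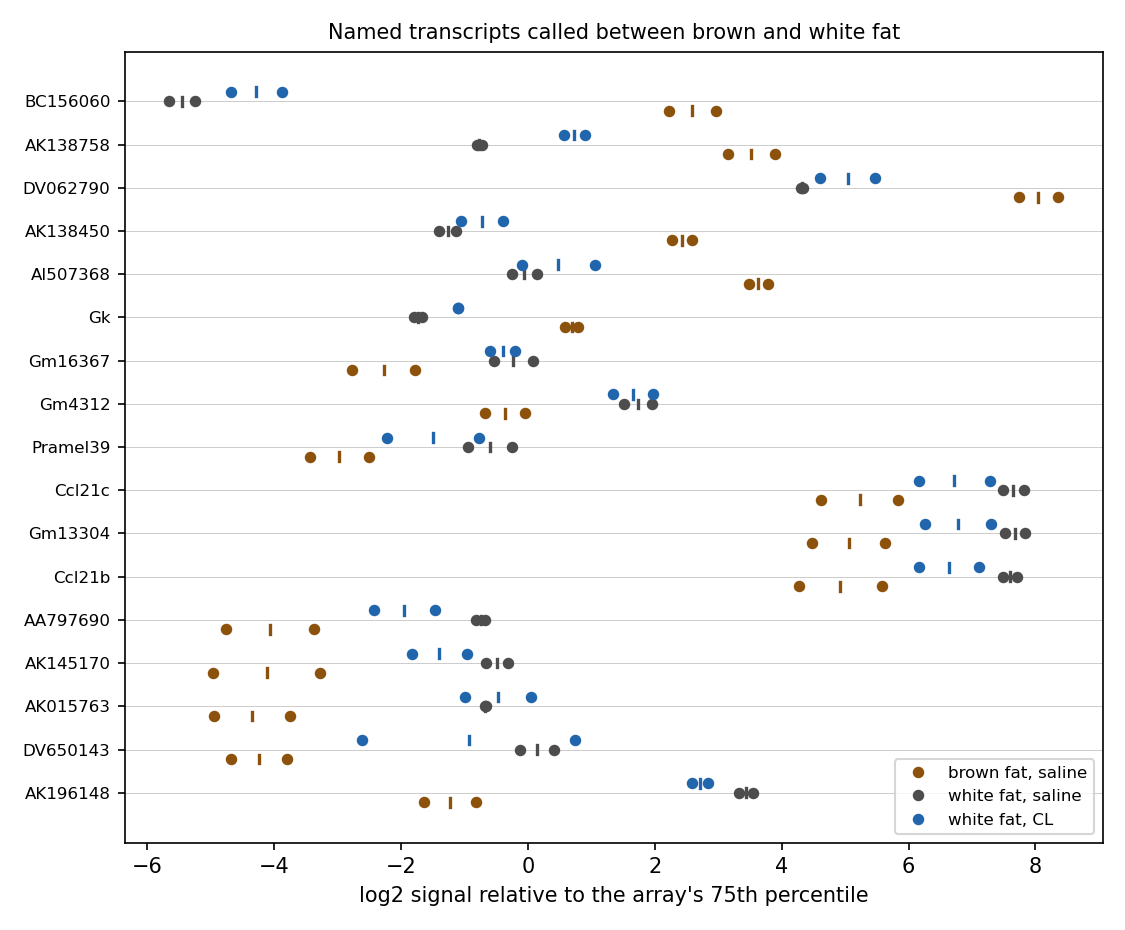
Log2 signal of the named transcripts on each tissue array (points) and group mean (bars), relative to the array's 75th percentile. Transcripts not well above background in a group have only a bound there, so the order shown is not a ranking. AK138758 was 19.5-fold higher and AK196148 25.3-fold lower in brown fat.

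Over all 43542 probes tested, 4526 were called, 2408 higher and 2118 lower in brown fat, and the called probes were all at least 2-fold apart. Non-coding probes leaned towards brown fat, with 1449 higher and 936 lower, while probes of the mRNA class leaned towards white fat, with 934 higher and 1151 lower (Fisher's exact odds ratio 1.91, 95% interval 1.69 to 2.15, p = 1.56e-26). The lean was widest for lincRNA probes, of which 248 were higher and 59 lower in brown fat (odds ratio 5.18 against the mRNA class, interval 3.83 to 7.09, Fisher's exact p = 9.26e-34). Without saline white fat replicate 1 the lean was weaker, with 47.4% of lincRNA calls higher in brown fat beside 38.0% of all calls. Too few lincRNA calls remained there to tell the classes apart. With array weights 69.3% of lincRNA calls were higher, beside 43.9% of all calls. Two-sided tests were used, and they treat probes as independent. Probes of ultraconserved elements were higher in 24 cases and lower in 7, and those of transcript accessions in 58 and 28. Under the deposited value table, which lists no mRNA-class probe, the split was 2698 higher and 998 lower, and under quantile normalization it was 3620 and 2154. The balance turned towards white fat with array weights (7155 higher, 9146 lower), in the 2 saline groups alone (6171 and 8055) and without any 1 array. Named after their values were seen, the lincRNA locus probe MM9LINCRNAEXON10825+ was higher in brown fat by log2 5.33 (SE 0.48) and MM9LINCRNAEXON10942+ was lower by log2 -4.17 (SE 0.47). Among probes with a design number alone, ASMM9PARTA029387 (log2 11.95, SE 0.62, limma adjusted p = 0.000692) and ASMM9PARTA009843 (log2 9.89, SE 0.41) were the furthest above white fat, and ASMM9PARTA042006 (log2 -9.09, SE 0.46; well above background on 1 of the 2 brown fat arrays) was furthest below it.

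The count of calls depended on single arrays. It was 321 or 637 without brown fat replicate 1 or 2, and 519 or 882 without saline white fat replicate 1 or 2. It was 14219 or 14224 without CL replicate 1 or 2 and 14226 in a fit of the 2 saline groups alone, because the CL pair enters the shared estimate of spread. The call of Gk was lost whenever a saline array was left out (limma adjusted p = 0.0675 to 0.11). So were the calls of Ccl21c, Gm13304, Pramel39, Gm4312, Gm16367 and DV650143 (0.0562 to 0.275), and that of Ccl21b without 3 of the 4 saline arrays (0.0917 to 0.189). With no filter all of these calls but that of Gk were lost too (0.059 to 0.0843), and those of Pramel39 with normexp (0.116) and DV650143 under quantile normalization (0.0569). AK145170 and AA797690 lost theirs without 3 of the saline arrays, and AK015763, AI507368 and DV062790 without brown fat replicate 1, while BC156060, AK138758, AK138450 and AK196148 passed the threshold without any 1 array.

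**Figure D2:**
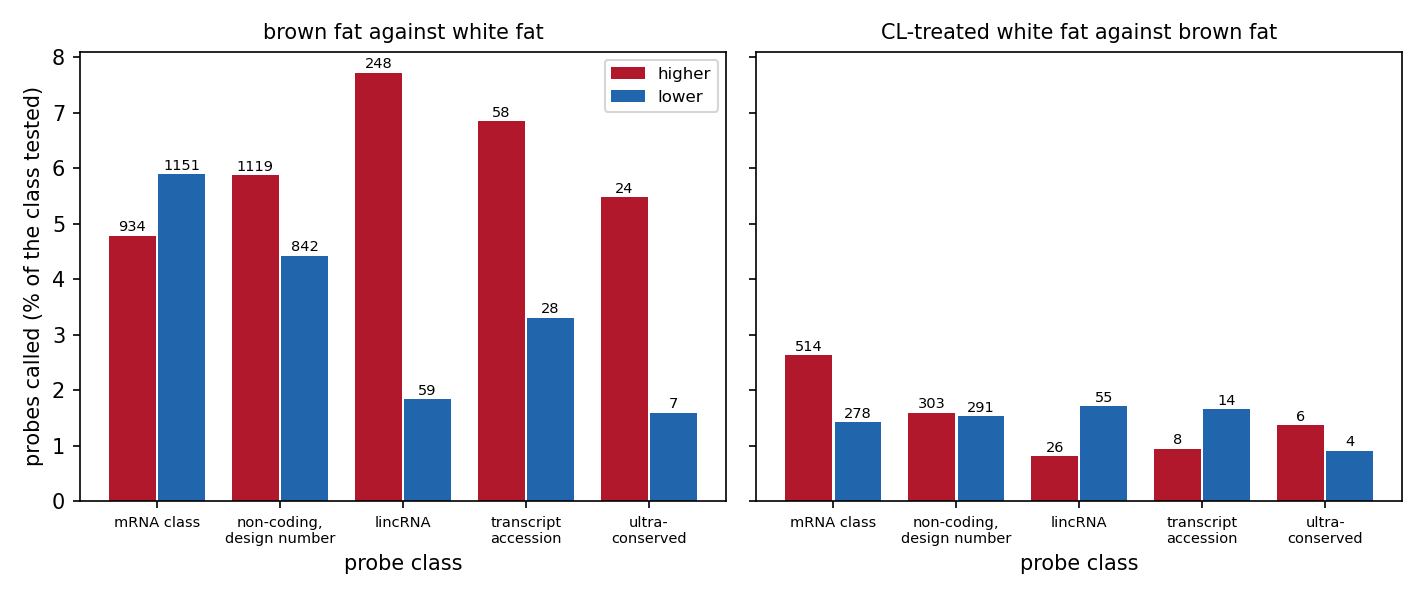
Probes called at adjusted p under 0.05, as a percent of the class tested on the vertical axis, per probe class, with the count above each bar. In the left panel 248 lincRNA probes were higher and 59 lower in brown fat. In the right panel 26 lincRNA probes were higher and 55 lower in CL-treated white fat than in brown fat.

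The second comparison asked how 7 days of CL changed white fat. No named transcript changed past the threshold. Gk stood at -1.10 ± 0.01 after CL against -1.73 ± 0.09 after saline (n = 2 each; log2 difference 0.63, SE 0.34, limma adjusted p = 0.952). AK138758, higher in brown fat, had a log2 difference of 1.50 (SE 0.40, limma adjusted p = 0.624) and AK196148 one of -0.72 (SE 0.41). BC156060 was not well above background on any white fat array, so no difference is given. By limma 0 of 43542 probes were called, 2378 had an unadjusted p under 0.05, and the smallest adjusted p was 0.173.

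That smallest value belonged to ASMM9PARTA029387, the probe furthest above white fat in brown fat, which was 7.43 (SE 0.62) higher after CL on the log2 scale. The lincRNA locus probe MM9LINCRNAEXON11065- followed, at 4.13 (SE 0.42) and a limma adjusted p of 0.28. ASMM9PARTA029387 was called with limma when only probes well above background on all 6 arrays were tested (adjusted p = 0.0109), where MM9LINCRNAEXON11065- was the other of the 2 calls (adjusted p = 0.0322). Without saline white fat replicate 2 there were 110 calls, 7 higher and 103 lower, and without saline white fat replicate 1 there were 4. With normexp correction there were 32, 14 higher and 18 lower. Over all tested probes the replicates of the treated group lay furthest apart of the 3 pairs.

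The third comparison set CL-treated white fat against brown fat, where tissue and treatment both differ. Gk stayed below brown fat, at a log2 difference of -1.79 (SE 0.34, limma adjusted p = 0.0387). BC156060 was at least 73.3-fold lower than in brown fat (limma adjusted p = 0.00156), and BB791535 and AI427689, also not well above background on either treated array, were at least 12.7-fold and at least 3.94-fold lower. AK138450 and AI507368 were lower by log2 -3.15 and -3.15. AK196148 was 15.4-fold higher in treated white fat than in brown fat (log2 3.94, SE 0.41, limma adjusted p = 0.00631), AK015763 at least 7.43-fold higher and FJ387503 at least 2.01-fold higher, with AK038804 and AI530503 higher by log2 2.61 and 2.40. Gm4312 was higher by log2 2.02 (SE 0.42, limma adjusted p = 0.0488). With normexp the log2 differences were -4.583 for BC156060, -2.258 for BB791535, -1.445 for AI427689, 1.49 for AK015763 and 0.478 for FJ387503, each smaller than its bound. The calls of Gk and Gm4312 were lost with no filter (limma adjusted p = 0.0865 and 0.0984) and without any 1 saline array (0.0816 to 0.361), and that of Gm4312 under quantile normalization (0.0552). Without either brown fat array the calls of AK138450, AI507368, AI530503, FJ387503 and AK038804 were lost, those of AI530503 and AK038804 also with no filter and that of FJ387503 also with normexp. BB791535 lost its call without brown fat replicate 2 and AK015763 without replicate 1.

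Of 43542 probes, 1521 were called, 864 higher and 657 lower in treated white fat. Of these, 1276 were also called between saline white fat and brown fat, a comparison that shares the brown fat arrays with this one and is no independent evidence. Of lincRNA probes 26 were higher and 55 lower in treated white fat (odds ratio 0.256 against the mRNA class, interval 0.151 to 0.426, Fisher's exact p = 1.45e-08). The count was 203 or 292 without brown fat replicate 1 or 2, 2361 or 11522 without CL replicate 1 or 2, and 994 or 995 without saline white fat replicate 1 or 2. The balance turned under the value table (418 higher, 856 lower), with probes well above background on all 6 arrays (1012 and 1147), with only probes of the value table (497 and 742), and without brown fat replicate 1 (84 and 119) or CL replicate 2 (5624 and 5898).

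Whether CL moved white fat towards brown fat was examined across probes. Of the 4526 probes called between brown and white fat, 3843 (84.9%) had CL values on the brown fat side of saline white fat. Both comparisons use the same saline white fat arrays. With no CL effect simulated the share was 63.0% (60.9% to 64.4% over 100 draws). That range is the spread between simulated draws, not between samples, so 84.9% lying outside it is not clear evidence of a move. With 1 saline white fat array in the brown-white difference and the other in the CL difference, the share depended on the CL array. In the order of saline replicates 1 and 2 for the brown-white difference, it was 64.5% and 76.5% for CL replicate 1. For CL replicate 2 it was 85.7% and 85.3%. The probes counted were called with both saline white fat arrays, so these shares are not free of the shared arrays. No share without a CL effect was simulated for this split. Over all tested probes, called or not, 67.9% of the 2 differences had the same sign, beside 66.7% simulated without effects. The covariance of the differences across all tested probes was 0.349 beside 0.123 simulated without effects (correlation 0.487 beside 0.500), a difference of covariances of 0.226. The spread of the saline white fat pair itself gave 0.0751 in place of 0.123. With no array shared the covariances were 0.129 and 0.417 for CL replicates 1 and 2.

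With the saline white fat arrays kept apart, so that no array entered both differences, CL replicate 2 moved along the brown-white difference with slopes of 0.269 and 0.302, and CL replicate 1 with slopes of -0.00 and 0.198. The 2 saline arrays cannot be split into sets of 2, so part of the excess may come from the shared controls. Without saline white fat replicate 1 the difference of covariances was 0.0017, and without CL replicate 1 it was 0.435.

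The fourth comparison followed brown adipocytes through differentiation, with 1 array per day and no replicate check. BX523225 was 72.0-fold higher at day 7 than at day 0, passing from log2 -0.90 at day 0 through 3.31 and 3.83 to 5.28. AK217121 and AI530503 were higher at day 7 by log2 3.30 and 3.31, and had differed by 3.35 and 3.18 at day 3. BB691294 and BC060946 were not well above background at day 0 and were at least 3.93-fold and at least 2.41-fold higher at day 7. AF416735 differed from day 0 by log2 -5.78 at day 3 and -3.55 at day 7, and AK018648 by -3.74 at day 7. BY669304, AA607596 and BU962981 were not well above background at day 7 and were at least 2.55-fold, at least 2.05-fold and at least 1.57-fold lower than at day 0. With normexp the log2 changes were 0.981 and 0.744 for BB691294 and BC060946, and -0.911, -0.616 and -0.581 for BY669304, AA607596 and BU962981, all smaller than these bounds.

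Among symbol-bearing probes, Amy2a5, an amylase gene with near-identical copies, was 5.79-fold higher at day 7, and G6pd2, a retrocopy of the gene for glucose-6-phosphate dehydrogenase, was 2.95-fold higher, and neither probe can be assigned to 1 copy with certainty. With normexp correction the log2 change of Amy2a5 moved from 2.533 to 1.096, and that of Pramel39, below, from -1.35 to -0.56. Of 66 alternative values for the 30 probes followed, 18 moved, all with normexp, and 0 turned direction. Csprs differed from day 0 by log2 -3.68 at day 7, Ppp2r3d, a regulatory subunit of a protein phosphatase, by -1.68 and Aida by -1.43. Vamp7, a SNARE protein of vesicle fusion, was lower by log2 -1.40, Pramel39 by -1.35 and Actb, cytoplasmic actin, by -1.16, and Actb had its lowest value at day 3. Of the 97 symbol-bearing probes measured in the cells, 2 were raised, 7 lowered and 88 neither. Of the transcripts higher in brown fat, Gk differed between days 0 and 7 by log2 -0.14, AK138758 by 0.32 and DV062790 by 0.34, and AK196148, higher in white fat, by 1.93.

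**Figure D3:**
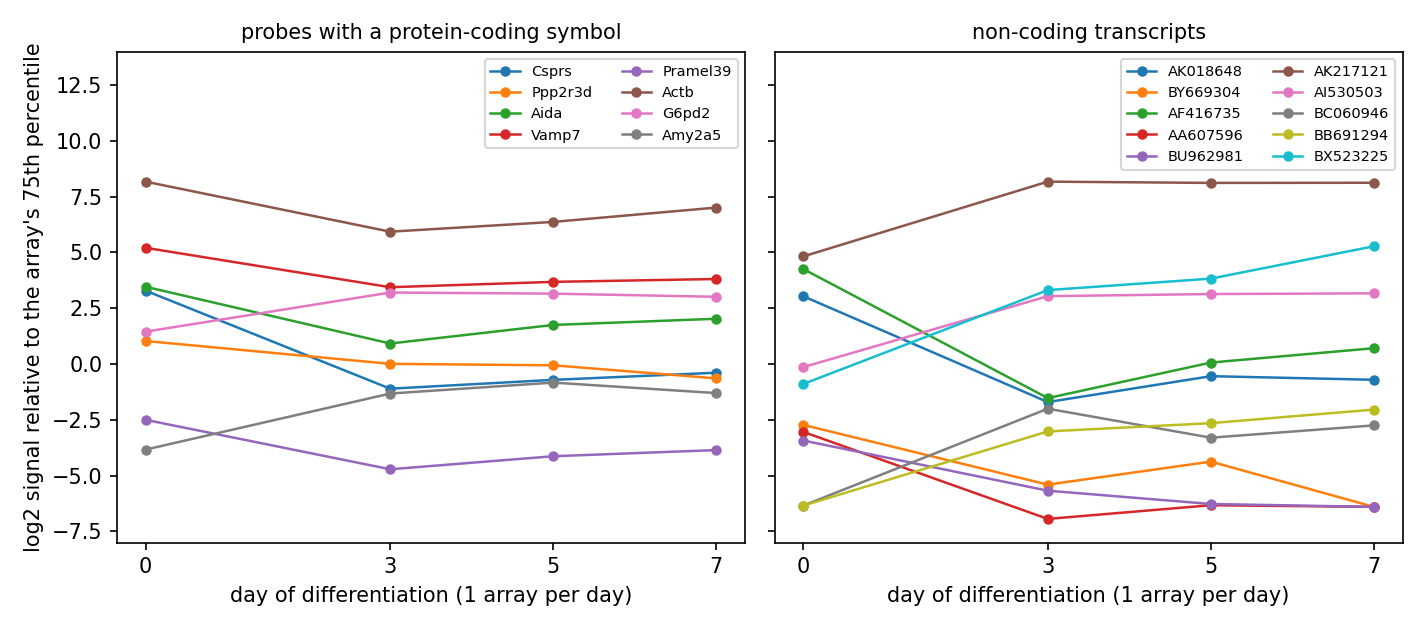
Log2 signal, relative to the array's 75th percentile, of the named probes against the day of differentiation (1 array per day), with symbol-bearing probes on the left and non-coding transcripts on the right. The probes were chosen for being at least 2-fold from day 0 on each of days 3, 5 and 7, so an early step was required. At day 3 AF416735 differed from day 0 by log2 -5.78 and AK217121 by log2 3.35.

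Of 48630 probes, 2602 were raised and 3014 lowered by at least 2-fold on each of days 3, 5 and 7. This balance depended on scaling and filter, with 2985 raised and 2615 lowered under quantile normalization, 3127 and 2503 with median scaling, 1118 and 583 under the value table, 1605 and 1568 with normexp, and 2037 and 1816 for probes well above background on all 4 arrays. Non-coding probes were raised in 1309 cases and lowered in 1448, and mRNA-class probes in 1252 and 1517. Of 3926 lincRNA probes 85 were raised and 185 lowered. The day 0 array is the baseline of every count. Its 95th percentile of negative control signals was 148, beside 83.1, 67.7 and 70.7 at days 3, 5 and 7. Under the filter at the 95th percentile of negative controls, chosen after seeing the data, 2274 probes were raised and 1745 lowered. The lowered count fell more than the raised count, and the balance turned towards raised probes. The excess of lowered probes was therefore not seen once dim probes were left out. Whether the higher control signal at day 0 accounts for this was not tested. Among design numbers, ASMM9PARTA031791 (at least 7222-fold) and ASMM9PARTA037462 (log2 11.64) had the largest measured rises from day 0 to day 7. ASMM9PARTA039654 (at least 49.8-fold) and ASMM9PARTA044341 (at least 28.8-fold) were lower at day 7. Neither was well above background then, so these bounds are not a ranking. In the order named, the log2 changes with normexp were 10.892, 10.173, -3.998 and -3.187. As a scale of spread, day 5 had 3.27% of probes 2-fold above and 8.83% 2-fold below day 3, beside 4.42% to 35.0% of probes 2-fold apart in the replicate pairs of tissue. A limma trend on the day called 0 probes, with 4324 at an unadjusted p under 0.05.

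The last comparison asked which non-coding probes were both higher in brown fat and raised in differentiation, a set that both arms of the study point to. There were 83 such probes of 22665 measured in both arms, where independent lists of 1398 and 1151 probes would share 71.0 (odds ratio 1.19, interval 0.937 to 1.50, Fisher's exact p = 0.131). In the mRNA class 123 probes overlapped where 56.6 would by independence (odds ratio 2.51, interval 2.04 to 3.08, Fisher's exact p = 1.99e-16), and the odds ratio of the non-coding class was 0.475 times that of the mRNA class (interval 0.350 to 0.644, Woolf's test p = 1.67e-06). Probes lower in brown fat overlapped beyond independence with lowered probes, 130 against 34.0 in the non-coding class and 211 against 70.3 in the mRNA class, and with raised probes, 78 against 40.9 (odds ratio 2.08, Fisher's exact p = 4.45e-08) and 120 against 64.7 (odds ratio 2.08, Fisher's exact p = 3.37e-11). Probes higher in brown fat shared fewer with lowered probes than independence would give, 21 against 59.1 and 26 against 61.5. Among lincRNA probes 1 was higher in brown fat and raised, against 5.29. The count of 83 was 129 under quantile normalization, 37 with no filter, 12 to 23 without a saline array and 220 without a CL array.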

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

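The restriction to probes of the value table, the filter at the 95th percentile of negative controls, each CL array alone, each day left out, the blocked overlap and the lincRNA share under other settings were chosen after seeing the data. A slide block was not run, because all tissue arrays share 1 scan, and no gene list could be tested. Brown against white fat had 3045 to 6225 calls under quantile normalization, median scaling, normexp, the value table or its probes alone, both stricter filters, a 2-fold minimum, the trended prior and the replicate block. With normexp only 3204 of the 4526 main calls were among them. The value table shared 1820 and its probes alone 1826, but there 18944 probes were tested in place of 43542. The count of calls changed to 1385 with no filter (more probes tested), 16301 with array weights and 14226 with the compared groups alone. Leaving out 1 array gave 321 to 14224. CL against saline white fat, 0 in the main setting, had 32 calls with normexp, 2 with probes well above background on all 6 arrays, 2 with the trended robust prior, 1 with only probes of the value table, 1 above negative controls, 0 to 110 leaving out 1 array and 0 in the other settings except the replicate block. CL-treated white fat against brown fat, 1521, moved to 544 with no filter, 2606 with the trended prior, 265 with array weights, 2578 above negative controls, 995 with 2 groups and 203 to 11522 leaving out 1 array, where the lone array is assumed to vary like the others. With the replicate number as a block, counts were 6225 (2849 higher and 3376 lower, which turned the balance towards white fat), 1 (ASMM9PARTA029387) and 2196, and the overlap was 99. Same-numbered deviations correlated at -0.02 (saline white and brown fat), 0.50 (saline and CL white fat) and -0.08 (brown fat and CL), and the numbers were not taken to pair the samples, which for the 2 white fat groups stays open. Differentiation, 5616, moved to 3173 with normexp, 1701 in the value table, 1935 at 4-fold, 10524 for day 7 alone and 0 for the limma trend, and was 3853 to 7565 otherwise. The overlap of 83 moved to 129 with quantile normalization, 37 with no filter and 12 to 220 leaving out 1 array. The covariance difference of 0.226 ranged from 0.0017 to 0.435 leaving out 1 array, and was 0.0822 with normexp. Normexp moved the median difference of all probes between brown and white fat from -0.12 to 0.10. Of 316 alternative values for 29 named probes between brown and white fat, 250 kept their side of the threshold and 66 lost the call, 54 of them by leaving out 1 array; 0 turned direction. Of 262 values for 24 probes between CL-treated white and brown fat, 43 lost it, 30 by leaving out 1 array. Median scaling, array weights, the trended prior and the fit of 2 groups were not followed for the named probes, except reference genes under median scaling. For CL against saline white fat the 2 calls with the trended robust prior were ASMM9PARTA029387 and MM9LINCRNAEXON11065- (limma adjusted p = 0.042 each). Signal over background limits dim probes, which have only bounds, and up to 36.4% of negative control spots passed the same mark. Causes of these changes were not tested unless stated.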

Other observations

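Of the tests in this part, that of a different size of the CL response and the lincRNA share under other settings were chosen only after the result was seen. Among genes often used as references, Ppia differed between brown and white fat by log2 0.10 (-0.33 under quantile normalization, where its direction flips) and B2m by -0.23, while Gapdh differed by 1.09 and Hprt by -1.11, with the same directions under quantile normalization and median scaling, and none of these was called (limma adjusted p = 0.107 to 0.901). In the cells Tfrc, the transferrin receptor, was higher at day 7 than at day 0 by log2 1.15 and Actb lower by log2 -1.16, in the same directions under both other scalings.

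The 2 arrays of CL-treated white fat lay further apart than the other replicate pairs. After quantile normalization 26.3% of tested probes were still 2-fold apart in the CL pair, against 9.38% in brown fat, which argues against array brightness and scaling as the whole cause. An 8 by 8 grid of spot positions took 0.00472 of the variance of their difference, which argues against uneven hybridization across the surface. The difference CL replicate 2 minus CL replicate 1 correlated at 0.222 across probes with the brown-white difference, with which it shares no array, between the bounds set for and against a different size of response. A different response of the 2 samples, another dissection and RNA quality stay open.

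lincRNA probes called between brown and white fat were mostly higher in brown fat, 80.8% of 307. In 1000 draws of mRNA-class probes matched on level the share of higher calls was 34.9% to 46.1% over the central 95% of draws, so a bias tied to dim probes does not account for it. Under quantile normalization 85.5% were higher. That scaling also raised the share of all calls that were higher, from 53.2% to 62.7%, so the lincRNA share alone does not test scaling. The lean against the mRNA class remained under quantile normalization and median scaling (Fisher's exact p = 3.19e-37 and 2.08e-34). Without saline white fat replicate 1 the share was lower, but too few lincRNA calls remained to tell whether the lean rests on that array. That brown fat may hold more lincRNA transcripts than white fat is a hypothesis found and tested on the same arrays. RNA quality, cell makeup and slide row were not tested.

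Probes for opposite strands of a lincRNA locus moved together only weakly between brown and white fat, at r = 0.110 over 994 loci, where the highest of 1000 shuffled pairings reached 0.0979. Both strands were called at 12 loci, 11 of them in the same direction, and exactly 1 strand at 170 (odds ratio of both called 1.36, Fisher's exact p = 0.365). Of 1328 bright strands, a share of 0.400 had the other strand well above background on all 6 arrays. That argues against signal that does not depend on strand, such as genomic DNA, as the whole source of the lincRNA values. A part from such signal stays open. At the named locus MM9LINCRNAEXON10942 both strands were lower in brown fat. The - strand, not well above background there, was at least 6.80-fold lower (log2 -1.586 with normexp).

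ASMM9PARTA029387, chosen after its values were seen, had 9.05 and 8.56 in brown fat, -2.31 and -3.98 in saline white fat and 4.80 and 3.77 in CL-treated white fat. The files pair this probe with no gene.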
